A study of Marchantia polymorpha with 9 samples.

How the data were processed

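Gene expression was measured by RNA sequencing of 9 libraries from 3-week-old plants, 3 of the Mpb-gata1-1 mutant, 3 of the Mpb-gata1-2 mutant and 3 of BoGa, made with a stranded mRNA kit per the labels' protocols. Groups and replicate numbers come from the labels. The deposited table of each library lists 20574 genes with their positions. Per the file headers, the columns hold total gene reads and unique gene reads, which are counts with no normalization by the authors, and TPM and RPKM values calculated by the authors. TPM has the same sum in each library, and both TPM and RPKM divide by the whole gene region with its introns, as the deposited gene lengths show. The aligner, the genome build, the annotation version, the treatment of reads that fit several genes and the use of strand are not given in the sources used here. Positions are as in the deposited tables. Total gene reads include reads shared with other genes, so values of close paralogs and of overlapping genes are less certain, and the share of unique reads is given where it is under 90%.

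Depth was 24823337 to 44133919 gene reads per library. A floor of 3 reads over the 3 libraries of a group was used for genes without reads in it, and for genes with 1 read the ratio is given with a 95% interval. No per-sample columns of other samples were present.

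Gene names were taken by locus number from a table of the MpTak2_v7.1 assembly. Of the 20574 genes, 17641 (85.7%) matched, and 3090 had a symbol. As a check, 81.4% of the matched genes had a length within 20 bp of that in the table, against 0.924% when the match was shifted by 1 gene. No positions were taken from that table.

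Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr by group were kept (14667 tested and 5907 not tested), and libraries were scaled by TMM. The quasi-likelihood test with robust estimation was used on a model with a term for each group and no other covariate, with all 9 libraries sharing an estimate of the spread. The biological coefficient of variation was 9.08%. Contrasts were each mutant minus BoGa, the mean of both mutants minus BoGa, and Mpb-gata1-2 minus Mpb-gata1-1. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene passed at an adjusted p under 0.05. Log2 changes are fitted values, and CPM values are TMM-scaled means ± SD of 3 libraries. The test was tested on simulated data of 14543 tested genes, with 200 genes changed in each mutant, independently and in random directions. For Mpb-gata1-1 against BoGa it recovered 59.4% of the 1.5-fold, 90.0% of the 2-fold and 95.4% of the 4-fold changes, and for Mpb-gata1-2 against BoGa 62.7%, 79.6% and 96.0%. Of the genes called, 5.23% and 5.39% were false. Far more genes passed in the real data, so the simulation cannot test the scaling or the balance of higher and lower genes there.

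Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), two-sided, with a preset correlation between genes of 0.01, adjusted over the 51 lists with at least 5 tested members. None of the lists that passed did so with an estimated correlation. The lists were fixed before the data were examined as patterns for gene products. Because the name table gives symbols and few products, they were rewritten as families of symbols after that table had been seen and before any test, which left the early light-induced, light-harvesting antenna, starch, ribosomal, organelle and U-chromosome lists without members to test. Symbols of cell-type genes were treated in the same way. Counts of list members that passed are over all genes tested and, where said, adjusted over the list alone.

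Genes to name were chosen by a rule fixed with the design. It takes the GATA genes, the 12 largest rises and 12 largest falls with a name that changed alike in both mutants with all 6 mutant libraries on one side of BoGa, the 5 largest in each direction for each mutant and for the difference between the mutants, and up to 4 members of each list with called members in order of p. It requires a mean log2 CPM of at least 1 for the ranked genes, and adds 2 rises and 2 falls without a name. It gave 233 genes. The text names 99 genes, which are all of the ranked genes, the cell-type genes and, for the lists described, the first members in order of p.

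Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean log2 CPM of at least 1), only the groups compared, the replicate number as a block, fold thresholds of 1.5 and 2, an adjusted p under 0.01, limma on log2 of TPM or RPKM plus 1 or 0.1, unique reads, and leaving out each library. The V level as a covariate and leaving out V-chromosome genes were added after the data had been seen. Overlap and correlation between the mutants were set beside 20 simulations. In these all 9 libraries were drawn without an effect, and both mutants were compared with the same simulated BoGa libraries. Other splits of the libraries were drawn, at most 100 for each result. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.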

Results

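RNA sequencing libraries were made from whole 3-week-old thallus plants of the liverwort Marchantia polymorpha. The wild type was BoGa, and the libraries labelled Mpb-gata1-1 and Mpb-gata1-2 came from mutants of MpB-GATA1. B-class GATA genes encode zinc finger transcription factors, and in flowering plants they are known to promote greening and to respond to light and cytokinin. Each of the 3 groups had 3 libraries, and each library came from 3 pooled plants, so the p-values measure the spread between such pools. The plants had grown at 22 °C in cycles of 16 h light and 8 h dark. The tables gave 24823337 to 44133919 gene reads per library, of which 98.2 to 98.3% mapped to a single gene. Of 20574 genes, 14667 had enough reads to be tested.

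Libraries of the same group resembled each other more than libraries of different groups. Across genes, Pearson's r of log2 CPM (counts scaled to library size) was 0.989 to 0.995 within groups and 0.947 to 0.961 between them. No pair of replicates differed by as little as the sampling noise, since the chi-square per degree of freedom was 8.28 or more in each of the 9 pairs.

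**Figure D1:**
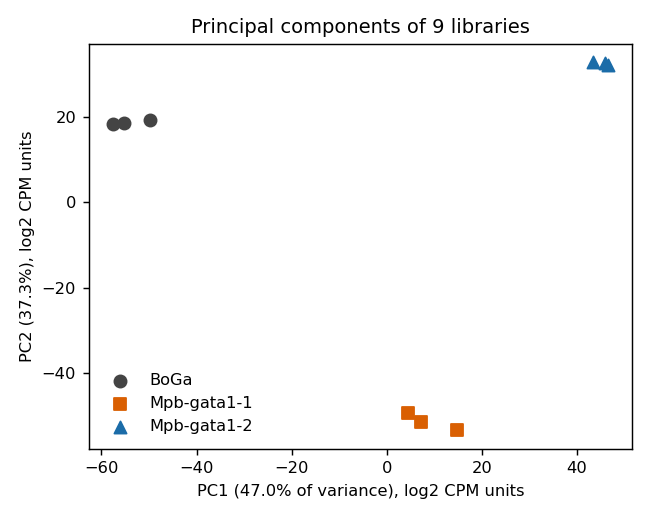
Principal components of log2 CPM in the 9 libraries, with each point a library and each group in its own colour and marker. PC1 held 47.0% and PC2 held 37.3% of the variance, and the 3 groups lie apart.

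The level of genes on the V chromosome, the sex chromosome of male plants, differed between the groups. The V level of a library was the median of 22 V genes relative to their mean in Mpb-gata1-2. These were the genes with a mean of at least 1 CPM and at least 95% unique reads. The V level was 0.0206 ± 0.00419 (SD, n = 3) in Mpb-gata1-1 and 0.946 to 1.03 in Mpb-gata1-2. In BoGa it was 0.527 ± 0.157 (SD, n = 3), and the BoGa libraries stood at 0.368, 0.533 and 0.682. Over all V genes, shared reads included, the share of gene reads differed less. It was 0.175 to 0.396% in Mpb-gata1-1, 0.286 to 0.382% in BoGa and 0.440 to 0.806% in Mpb-gata1-2. Genes of the U chromosome, its counterpart in female plants, were not analysed here.

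**Figure D2:**
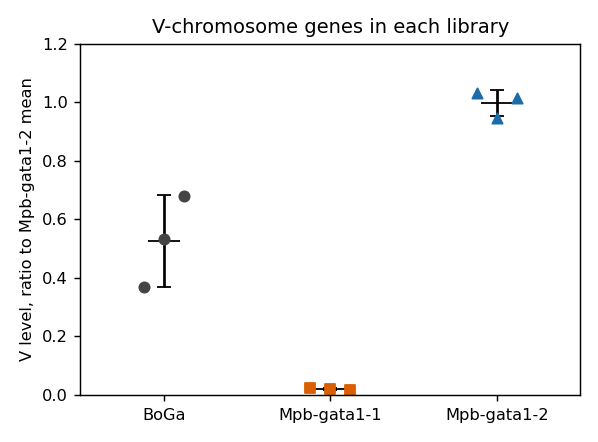
V level of each library (points), as a ratio to the Mpb-gata1-2 mean, with the mean and SD of each group (n = 3). The Mpb-gata1-1 libraries sit between 0.0172 and 0.0253, and the BoGa libraries between 0.368 and 0.682.

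The GATA genes were examined first. MpGATA4 (Mp7g03490; chromosome 7, 4342060 to 4345887, plus strand) is taken here to be B-GATA1 from knowledge of the study, since neither the tables nor the gene name list pairs the names. Its level was 151 ± 3.37 CPM in BoGa, 252 ± 5.07 CPM in Mpb-gata1-1 and 283 ± 3.64 CPM in Mpb-gata1-2 (SD, n = 3), with the 6 mutant libraries above the 3 BoGa libraries. Across both mutants it rose by 0.82 ± 0.04 (log2, SE; adjusted p = 4.45e-07), with a rise of 0.74 in Mpb-gata1-1 and of 0.91 in Mpb-gata1-2. The labels do not describe the lesions, and an edited gene may still be transcribed, so these levels do not show which allele a library carries. MpGATA5 (Mp5g09130) fell by 0.53 across both mutants (adjusted p = 0.00023), from 48.4 ± 6.67 to 30.1 ± 1.35 and 37.2 ± 0.996 CPM, and MpGATA1 (Mp1g05310) rose by 0.23 (adjusted p = 0.00922), with a rise of 0.35 in Mpb-gata1-1 and a change in Mpb-gata1-2 that did not pass (0.12, adjusted p = 0.189). MpGATA2 (Mp1g03950) had a log2 difference of -0.33 that did not pass (adjusted p = 0.0626), but it passed with DESeq2 (0.0497), upper-quartile factors (0.0499996) or the V level as a covariate (0.0427), and without BoGa replicate 1 (0.0241) or BoGa replicate 2 (0.0455). MpGATA5 and MpGATA2 each overlap another gene on the same strand, which makes their counts less certain.

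**Figure D3:**
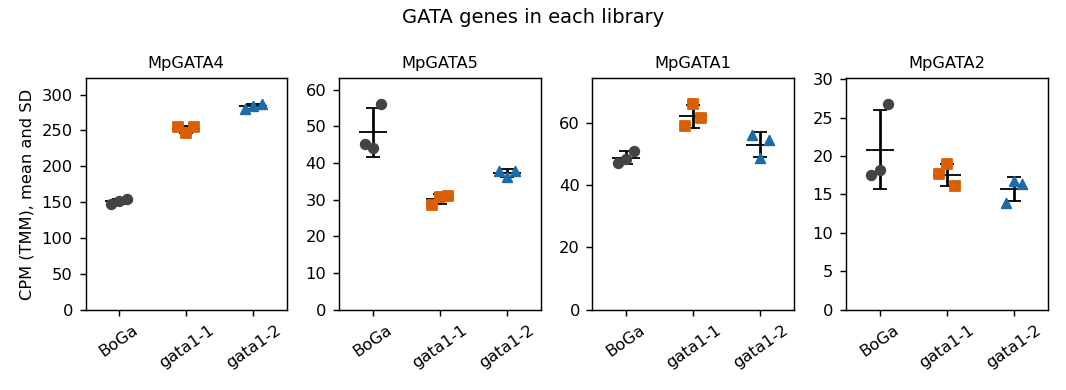
CPM of the 4 GATA genes in each library (points), with the mean and SD of each group (n = 3). MpGATA4 lies at 147 to 154 CPM in BoGa and at 246 to 287 CPM in the mutant libraries.

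The effect of the mutations in MpB-GATA1 was addressed by comparing the mean of both mutants with BoGa, so a gene counted here need not have changed in each mutant. With 1 line for each allele, this comparison cannot separate the mutations from the genetic background of the lines. Of 75 tested genes linked to water deficit and abscisic acid, 56 were higher and 8 lower, although the list did not pass with an estimated correlation between genes (adjusted p = 0.718). Several of the named genes with large rises, many of them from low levels, encoded late embryogenesis abundant (LEA) proteins, which protect cells during drying. MpLEA-like9 (Mp2g26450) went from 1.92 ± 0.719 CPM in BoGa to 33.9 ± 7.76 in Mpb-gata1-1 and 58.3 ± 6.89 in Mpb-gata1-2 (SD, n = 3), a rise of 4.53 ± 0.23 on the log2 scale (SE; adjusted p = 5.29e-07). The lists of pathogenesis-related proteins, cupins, cytochrome P450s and the cell cycle held more lower than higher genes, and the autophagy list more higher than lower genes. These lists and that of water deficit passed the camera test, but none of them did with an estimated correlation between genes (adjusted p = 0.718 to 0.899). In all, 7154 genes passed the test in edgeR at an adjusted p under 0.05, with 3330 higher and 3824 lower, and 1118 of them differed at least 2-fold (422 higher and 696 lower). The split between higher and lower depended on the scaling: with limma on the authors' TPM values 4582 genes were higher and 2545 lower, and on their RPKM values 3970 were higher and 3049 lower.

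Of the 75 tested genes of the water deficit and abscisic acid list, 56 rose and 8 fell (56 and 8 adjusted over the list alone), with a median log2 change of 1.81. The list passed the camera test (adjusted p = 2.64e-13), although not with an estimated correlation (adjusted p = 0.718 with an estimated correlation). Several of its genes lie close together on chromosome 6, between positions 3398849 and 3515363: MpLEA-like34 (Mp6g02970) rose by 4.65, MpLEA-like36 (Mp6g02990) by 4.21, MpLEA-like42 (Mp6g03090) by 5.83, MpLEA-like43 (Mp6g03100) by 5.20 and MpLEA-like44 (Mp6g03110) by 4.49. MpLEA-like36 stood at 1.06 ± 0.117 CPM in BoGa, 15.2 ± 3.94 in Mpb-gata1-1 and 26.2 ± 2.79 in Mpb-gata1-2 (SD, n = 3). The fitted change of MpLEA-like42 rests on 7 reads in the BoGa libraries. MpLEAL6 (Mp5g05120) rose by 4.19, MpLEA-like2 (Mp1g01170) by 3.16 and MpLEAL7 (Mp2g26410) by 4.25, but only 45.9% of the reads of MpLEAL7 were unique and it overlaps another gene. MpLEA-like34 had 84.6% unique reads.

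Other large rises included MpCALEOSIN (Mp5g05270), which encodes a lipid droplet protein, and MpCAT1 (Mp7g09020), a catalase. MpCALEOSIN rose by 4.22, from 0.252 ± 0.11 CPM to 3.69 ± 1.34 in Mpb-gata1-1 and 6.37 ± 0.673 in Mpb-gata1-2, and MpCAT1 rose by 4.54, from 0.268 ± 0.0698 to 4.29 ± 1.48 and 9.19 ± 0.857 CPM (SD, n = 3). The glycoside hydrolase genes MpGH16.17 (Mp3g10400) and MpGH3.5 (Mp5g02880) rose by 5.28 and 4.40, and the microbial-type terpene synthase gene MpMTPSL2 (Mp3g18500) rose by 4.25. The unnamed gene with the largest rise, Mp4g00760, had no reads in BoGa and 1110 and 1222 reads in the mutants, at least 363-fold higher in Mpb-gata1-1 and at least 418-fold higher in Mpb-gata1-2, against a floor of 3 reads over the group. Its neighbour Mp4g00740 was at least 316-fold and at least 413-fold higher. Such floors, and the intervals on ratios, cover counting error only.

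Of 27 tested pathogenesis-related genes, 18 were lower and 2 higher in the mean of the mutants (18 and 2 adjusted over the list alone), with an adjusted p of 0.000808 (adjusted p = 0.718 with an estimated correlation). MpPR15c (Mp2g01620) fell by 5.02, from 9.61 ± 2.71 CPM in BoGa to 0.31 ± 0.116 in Mpb-gata1-1 and 0.293 ± 0.191 in Mpb-gata1-2 (SD, n = 3), and 86.5% of its reads were unique. MpPR1m (Mp5g12510) fell by 1.07, MpPR1l (Mp4g16750) fell by 3.33 and MpPR1a (Mp1g08990) fell by 2.51. The proteinase inhibitor genes MpPR6a (Mp8g09630) and MpPR6b (Mp8g12150) fell by 3.43 and 3.38, from BoGa levels that varied widely (11.1 ± 8.31 and 8.92 ± 8.07 CPM). For MpPR6c (Mp8g12160) the BoGa libraries held 738 reads and the Mpb-gata1-1 libraries 1 read, a ratio of 753 (95% interval 135 to 29792), and across both mutants its fitted value fell by 5.53. Under the stricter filter on low counts, the list no longer passed (adjusted p = 0.0791).

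Among 64 cupin genes, which encode a family that includes germin-like and seed storage proteins, 35 fell and 7 rose (36 and 7 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.718 with an estimated correlation). MpCupin16 (Mp2g01930) fell by 1.19, MpCupin43 (Mp2g23430) by 0.69 and MpCupin63 (Mp5g00860) by 2.36. MpCupin6 (Mp2g01530) fell by 1.14 in the mean of the mutants, although its levels were 34.2 ± 1.09 CPM in BoGa, 34 ± 5.75 in Mpb-gata1-1 and 7.08 ± 0.579 in Mpb-gata1-2 (SD, n = 3), and 54.0% of its reads were unique. MpCupin8 (Mp2g01550) had no reads in Mpb-gata1-2, at least 219-fold lower than in BoGa, and stood at 6.63 ± 0.452 CPM in BoGa and 3.97 ± 0.631 in Mpb-gata1-1, with 20.4% unique reads.

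Of 34 cell cycle and DNA replication genes, 16 fell and 1 rose (18 and 2 adjusted over the list alone), with a median of -0.25 and an adjusted p of 0.0281 (adjusted p = 0.718 with an estimated correlation). MpSMR (Mp1g14080), which belongs to a family of inhibitors of cyclin-dependent kinases, fell by 0.73 from 33 ± 4.65 CPM to 19.8 ± 1.5 in Mpb-gata1-1 and 20.1 ± 1.23 in Mpb-gata1-2 (SD, n = 3). MpE2F (Mp1g02890), a transcription factor of the cell cycle, fell by 0.47, and MpCDC5 (Mp1g10310) fell by 0.26. Without Mpb-gata1-2 replicate 3 the list did not pass (adjusted p = 0.0515).

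Cytochrome P450 genes fell more often than they rose, with 46 of 107 lower and 15 higher (47 and 15 adjusted over the list alone), a median of -0.22 and an adjusted p of 0.0382 (adjusted p = 0.718 with an estimated correlation). MpCYP829-like12 (Mp2g18440) fell by 1.75, from 24.4 ± 4.02 to 3.88 ± 0.339 CPM in Mpb-gata1-1 and 13.5 ± 0.218 in Mpb-gata1-2 (SD, n = 3). MpCYP822-like6 (Mp5g10500) fell by 1.12, with 12 ± 1.12 CPM in BoGa, 11.5 ± 0.9 in Mpb-gata1-1 and 2.62 ± 0.151 in Mpb-gata1-2. The list did not pass under the stricter filter (adjusted p = 0.137), without Mpb-gata1-1 replicate 1 (0.0509) or without Mpb-gata1-2 replicate 3 (0.0542).

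Some autophagy and glycosyltransferase genes rose by small amounts. Of 21 autophagy genes, 10 rose and none fell (adjusted over the list alone likewise 10), with a median of 0.14 and an adjusted p of 0.0201 (adjusted p = 0.899 with an estimated correlation). MpATG4 (Mp1g14510), which encodes a protease that processes ATG8, rose by 0.35, from 91 ± 2.26 CPM to 111 ± 2.38 in Mpb-gata1-1 and 121 ± 4.55 in Mpb-gata1-2 (SD, n = 3). MpATG16 (Mp7g17850) rose by 0.38 and MpATG18b (Mp1g05420) by 0.28. Of 79 glycosyltransferases other than UDP-glycosyltransferases, 25 rose and 6 fell (22 and 6 adjusted over the list alone), with a median of 0.11 and an adjusted p of 0.0406 (adjusted p = 0.843 with an estimated correlation). MpGT47.17 (Mp7g03580) rose by 0.76, MpGT8.5 (Mp2g12520) by 0.50 and MpGT77.1 (Mp1g13560) by 0.45. The autophagy list did not pass without BoGa replicate 3 (adjusted p = 0.122), and the glycosyltransferase list did not pass without BoGa replicate 1 (0.0701), BoGa replicate 2 (0.144), Mpb-gata1-1 replicate 2 (0.0653) or Mpb-gata1-2 replicate 3 (0.0542).

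**Figure D4:**
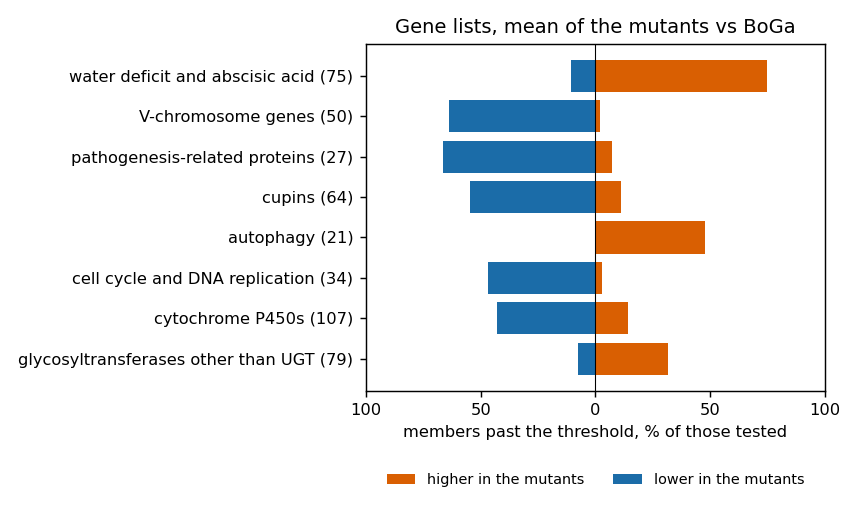
Share of the tested members (number in brackets) of each of 8 gene lists that were higher (right) or lower (left) in the mean of the mutants than in BoGa at an adjusted p under 0.05. The lists are those past the camera test, and 56 of 75 water deficit and abscisic acid genes were higher.

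Of 50 tested genes on the V chromosome, 32 were lower and 1 higher in the mean of the mutants (32 and 3 adjusted over the list alone; adjusted p = 0.000365, and adjusted p = 0.718 with an estimated correlation). By V level the mutants lay on opposite sides of BoGa, at 0.0206 in Mpb-gata1-1, 0.527 in BoGa and 0.946 to 1.03 in Mpb-gata1-2. Single genes such as MpVg00460 departed from this. MpVg00980 stood at 108 ± 33.4 CPM in BoGa, 0.178 ± 0.057 in Mpb-gata1-1 and 205 ± 10.9 in Mpb-gata1-2 (SD, n = 3). MpVg00600 stood at 48.9 ± 14.8, 0.261 ± 0.0528 and 104 ± 4.92 CPM. MpVg01150 had 6603 reads in BoGa and 1 in Mpb-gata1-1, a ratio of 6740 (95% interval 1209 to 266236). MpVg00460 had no reads in Mpb-gata1-1, at least 323-fold lower than in BoGa, and also fell by 3.46 in Mpb-gata1-2.

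Several groups held called members but did not pass as lists. In the list of photosynthesis, plastid and light protection genes, 7 of 14 were lower and 1 higher (7 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.165, and adjusted p = 0.718 with an estimated correlation). Of its members, MpCHLI1/2-like (Mp2g21150) and MpCHLD (Mp6g04260), which encode subunits of magnesium chelatase, fell by 0.43 and 0.38, and MpGUN4 (Mp6g06740), which encodes an activator of that enzyme, fell by 0.54. MpGUN4 went from 130 ± 6.31 CPM to 92.8 ± 10.4 in Mpb-gata1-1 and 86.2 ± 7.08 in Mpb-gata1-2 (SD, n = 3). Of 69 phenylpropanoid and flavonoid genes, 35 were lower and 14 higher (36 and 14 adjusted over the list alone; adjusted p = 0.115). MpDFR-like16 (Mp8g02830) fell by 2.09, from 98.1 ± 18.6 to 9.78 ± 0.751 CPM in Mpb-gata1-1 and 53.7 ± 5.88 in Mpb-gata1-2. The polyketide synthase genes MpPKS/CHS23 (Mp7g14960; 66.8% unique reads) and MpPKS/CHS14 (Mp4g14190) fell by 1.00 and 1.25, and 13 of 25 chalcone and stilbene synthase genes were lower and 3 higher (14 and 3 adjusted over the list alone; adjusted p = 0.103).

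The remaining large falls were in genes of other families. MpLOX16 (Mp2g16000), a lipoxygenase gene, fell by 2.79, from 25.5 ± 8.59 CPM to 4.62 ± 0.684 in Mpb-gata1-1 and 2.92 ± 0.196 in Mpb-gata1-2, and MpLOX4 (Mp5g21680) fell by 3.76, from 61.1 ± 8.4 to 0.993 ± 0.283 and 21.3 ± 4.17 CPM (SD, n = 3). MpPOD81 (Mp5g06880), a class III peroxidase gene, fell by 3.68, whereas its neighbour MpPOD80 (Mp5g06870; 87.7% unique reads) rose by 2.43. MpPOD160 (Mp7g19380) held 449 reads in BoGa and 1 in Mpb-gata1-2, a ratio of 437 (95% interval 78.0 to 17301). MpGH19.10 (Mp5g02110; 41.5% unique reads) fell by 3.79. The receptor kinase gene MpRLK-Pelle_WAK1 (Mp3g01920) fell by 4.37, but none of its reads were unique and it overlaps another gene. The unnamed genes Mp2g00015a and Mpzg01860a, which had no unique reads either, had 2066 and 2032 reads in BoGa and none in the mutants. They were at least 703-fold and at least 691-fold lower in Mpb-gata1-1, and at least 670-fold and at least 659-fold lower in Mpb-gata1-2.

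Among genes known from particular cell types or organs, MpGCAM1 (Mp6g04830), a MYB gene of gemma cup formation, rose by 1.93 from 5.15 ± 0.639 CPM to 15.3 ± 3.7 in Mpb-gata1-1 and 25.6 ± 3.91 in Mpb-gata1-2 (SD, n = 3). Of the other genes listed for gemma cups and gemmae, MpGRAS2 (Mp7g12630) rose by 0.43 and MpKAR (Mp5g06550) by 0.34 in the mean of the mutants. Neither of them passed in Mpb-gata1-1 alone (adjusted p = 0.104 and 0.0849). MpCLE2 (Mp5g18050) fell by 0.34, and the 4 genes stood at 5.15 to 37.3 CPM in BoGa. MpKAR did not pass without BoGa replicate 1 (adjusted p = 0.0955), BoGa replicate 2 (0.112) or Mpb-gata1-2 replicate 3 (0.0551). Of the rhizoid genes, MpBHLH14 (Mp3g17930) rose by 0.27, although not without BoGa replicate 2 (adjusted p = 0.0547) or in Mpb-gata1-2 alone (0.0618), and MpFRH1 (Mp1g06440) differed by 0.08 (adjusted p = 0.803). The oil body cell genes MpC1HDZ (Mp3g02320), MpSYP12B (Mp4g20670), MpERF13 (Mp6g08690) and MpABCG1 (Mp8g13070) did not pass (adjusted p = 0.228 to 0.757), although MpC1HDZ passed without BoGa replicate 3 (0.00257) and with the V level as a covariate (0.0371). Of 6 sexual branch and gamete genes, MpRKD (Mp3g04030) fell by 0.25. MpCEN1 (Mp1g00710) and MpMID (Mp1g11830) had a mean rise of 0.20 each, which came from Mpb-gata1-1 (0.34 and 0.44), since neither passed in Mpb-gata1-2 (0.07 and -0.05, adjusted p = 0.437 and 0.661). MpR2R3-MYB1 (Mp1g17210) fell by 3.76 in Mpb-gata1-1 and did not pass in Mpb-gata1-2 (0.61, adjusted p = 0.079), from 10.2 ± 4.56 CPM in BoGa (SD, n = 3), and its mean change of -1.58 lost its call with limma on log2(RPKM + 1) (adjusted p = 0.0818). MpDUO1 (Mp1g13010) and MpC2H2-3 (Mp4g11380) did not pass (adjusted p = 0.161 and 0.78). MpCEN1 did not pass without BoGa replicate 3 (adjusted p = 0.0605), and the mean change of MpMID passed narrowly (adjusted p = 0.0452). MpMID did not pass with DESeq2 (0.0540), upper-quartile factors (0.0653) or the V level as a covariate (0.0501), nor without any single BoGa library, Mpb-gata1-1 replicate 2 or 3, or Mpb-gata1-2 replicate 1 or 3 (0.0555 to 0.136). MpR2R3-MYB1 has a known antisense partner from which its reads cannot be told apart here, since use of strand in the counting is not given in the sources used here.

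The comparison of Mpb-gata1-1 alone with BoGa had LEA genes among its largest rises and defence and lipoxygenase genes among its largest falls. MpLEA-like42 rose by 5.46 (SE 0.55), from 0.0652 ± 0.0871 to 3.21 ± 1.04 CPM, MpLEA-like43 rose by 4.91, MpGH16.17 by 4.77, MpLEA-like34 by 4.51 and MpLEAL7 by 4.34. The cytochrome P450 gene MpCYP704-like8 (Mp3g10820) fell by 8.34 (SE 0.36), from 35.6 ± 10.6 CPM to 0.097 ± 0.0501 (SD, n = 3), and MpLOX4 fell by 5.998, MpPR15c by 5.02 and MpRLK-Pelle_WAK1 by 4.00, while MpPR6c was down to 1 read. In all 6746 genes passed, 3369 higher and 3377 lower, and 1229 differed at least 2-fold (486 higher and 743 lower), while limma on TPM gave 4541 higher and 2340 lower. With the V level as a covariate, a fit added after the data had been seen, 1856 genes passed and the median SE rose from 0.0938 to 0.243. The BoGa level of MpCYP704-like8 lay between those of the mutants, as the V level did, so its fall cannot be credited to the allele alone.

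Of the gene lists, water deficit and abscisic acid rose in Mpb-gata1-1 (55 of 75 higher and 6 lower, 58 and 6 adjusted over the list alone; adjusted p = 2.91e-12, and adjusted p = 0.702 with an estimated correlation). WRKY factors, many of which act in stress and defence, fell: 7 of 13 were lower and none higher (8 and 0 adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.702 with an estimated correlation). MpWRKY14 (Mp6g16800) fell by 1.62, from 15.5 ± 2.36 to 5.07 ± 0.685 CPM (SD, n = 3), and MpWRKY8 (Mp2g20960; 49.9% unique reads and an overlapping gene on the other strand) fell by 0.87. Expansins, which loosen cell walls, rose: 13 of 28 were higher and 3 lower (13 and 3 adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.758 with an estimated correlation). MpExpansin4 (Mp1g22730) rose by 0.78 and MpExpansin16 (Mp3g03970) by 0.73, whereas MpExpansin32 (Mp4g06560) fell by 0.87. The other lists past the test were V-chromosome genes (30 of 50 lower and 1 higher), pathogenesis-related proteins (19 of 27 and 4), cupins (28 of 64 and 12) and, with more higher than lower genes, autophagy (10 of 21 higher and none lower; adjusted p = 6.57e-11, 0.00168, 0.0209 and 0.0416, and adjusted p = 0.702, 0.702, 0.702 and 0.821 with an estimated correlation).

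In Mpb-gata1-2 against BoGa, LEA genes were again among the named genes with large rises, and more class III peroxidase genes, which encode secreted enzymes that oxidise phenolic compounds, fell than rose, although that list did not pass with an estimated correlation (adjusted p = 0.865). MpLEA-like42 rose by 6.19, MpGH16.17 by 5.79, MpLEA-like43 by 5.49, MpCAT1 by 5.09 and MpMTPSL2 by 4.98. MpPOD98 (Mp5g13650) fell by 7.45 ± 0.17 (log2, SE), from 36 ± 3.17 CPM to 0.214 ± 0.107 (SD, n = 3), and MpPOD153 (Mp7g14420) had no reads in Mpb-gata1-2, at least 68.8-fold lower than in BoGa. MpPR15c fell by 5.02. In all 6811 genes passed, 3190 higher and 3621 lower, and 1297 differed at least 2-fold (534 higher and 763 lower), while limma on TPM gave 4198 higher and 2546 lower. With the V level as a covariate, 1517 genes passed and the median SE rose from 0.0941 to 0.227.

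Of 138 tested class III peroxidases, 68 fell and 10 rose in Mpb-gata1-2 (72 and 12 adjusted over the list alone; adjusted p = 3.49e-05, and adjusted p = 0.865 with an estimated correlation). Polyphenol oxidases, which also act on phenolic compounds, fell, with 19 of 45 lower and 6 higher (23 and 7 adjusted over the list alone; adjusted p = 0.0327, and adjusted p = 0.972 with an estimated correlation). MpPPO4 (Mp2g05810) fell by 1.11, from 42 ± 5.18 to 19.4 ± 1.96 CPM (SD, n = 3), and MpPPO23 (Mp6g21120) rose by 1.04. Water deficit and abscisic acid genes rose with a median of 2.08 (54 of 75 higher and 8 lower, 55 and 9 adjusted over the list alone; adjusted p = 3.17e-13, and adjusted p = 0.599 with an estimated correlation). V-chromosome genes were higher (26 of 50, with 8 lower; adjusted p = 0.0167, and adjusted p = 0.972 with an estimated correlation). The lists of pathogenesis-related proteins (17 of 27 lower and 2 higher), cupins (30 of 64 and 10), cytochrome P450s (46 of 107 and 16), cell cycle genes (15 of 34 and 2) and autophagy (8 of 21 higher and none lower) also passed (adjusted p = 0.00446, 0.00875, 0.0116, 0.0157 and 0.0319, and adjusted p = 0.865, 0.599, 0.599, 0.599 and 0.972 with an estimated correlation).

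Genes that changed in both mutants in the same direction numbered 4015, with 1968 higher and 2047 lower (2775 and 1319 with limma on TPM), and in 3816 of them the 6 mutant libraries also lay on one side of the 3 BoGa libraries. The LEA genes MpLEA-like9 and MpLEAL6, the falling genes MpLOX16 and MpPR15c, and MpGATA4 and MpGATA5 were among them. A further 401 genes changed in opposite directions, MpPOD92 (Mp5g10750; 79.2% unique reads) and MpCupin35 (Mp2g05430; 86.6% unique reads) among them. Lists drawn independently would share 1566 genes of the same direction (733 higher and 834 lower). In 20 simulations all libraries were drawn without an effect, and at most 1 gene was shared. Few genes can pass in groups without an effect, so that count was near 0 by construction. Across genes, which are not independent replicates, the log2 changes had a Pearson's r of 0.530 and a Spearman's rho of 0.552, against medians of 0.504 and 0.453 in the simulations without an effect, and a covariance of 0.472 against 0.0202. Pearson's r lay within the range of those simulations, which reached 0.569. Without an effect, r comes from the noise of the shared BoGa libraries alone, so r cannot show whether there is an excess. The covariance is beyond the simulations, in which both mutants were compared with the same simulated BoGa libraries. The number of shared genes is beyond independent lists, which do not allow for common controls. A deviation common to the 3 BoGa libraries would still enter both comparisons, and the controls were not split to look for it. Over all genes tested, 4795 (32.7%) had the 6 mutant libraries on one side of the 3 BoGa libraries, where exchangeable libraries would give 2.38%. Libraries of the same group resemble each other and are not exchangeable, so this comparison does not measure the agreement of the mutants.

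**Figure D5:**
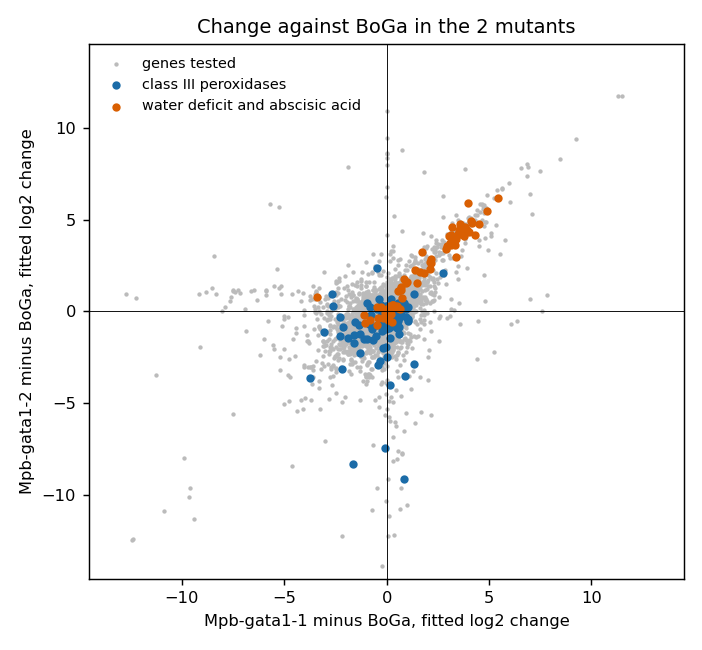
Fitted log2 change of each tested gene against BoGa in Mpb-gata1-1 (x axis) and Mpb-gata1-2 (y axis), with water deficit and abscisic acid genes and class III peroxidase genes in colour. Most of the former lie at the upper right, with medians of 1.498 and 2.08, and 68 of 138 peroxidase genes were lower in Mpb-gata1-2.

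The mutants were compared with each other to ask how far they share a transcriptome. Class III peroxidase genes were lower in Mpb-gata1-2 than in Mpb-gata1-1, with 83 of 138 lower and 16 higher (89 and 18 adjusted over the list alone; adjusted p = 2.00e-10, and adjusted p = 0.959 with an estimated correlation). MpPOD90 (Mp5g10730) stood at 59 ± 5.23 CPM in Mpb-gata1-1 and 3.26 ± 0.0713 in Mpb-gata1-2 (SD, n = 3), beside 52.9 ± 1.82 in BoGa, and MpPOD92 stood at 35.5 ± 2.83 and 1.69 ± 0.295, beside 19.3 ± 2.19. MpPOD153 was at least 125-fold and MpCupin8 at least 135-fold lower in Mpb-gata1-2, where neither had reads. In the other direction, MpCYP704-like8 stood at 69.2 ± 5.14 CPM in Mpb-gata1-2 and 0.097 ± 0.0501 in Mpb-gata1-1, MpLOX4 at 21.3 ± 4.17 and 0.993 ± 0.283, MpCupin35 at 11.8 ± 0.967 and 0.495 ± 0.0253, and MpR2R3-MYB1 at 15.5 ± 2.63 and 0.732 ± 0.16.

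Polyphenol oxidases and expansins were also lower in Mpb-gata1-2 than in Mpb-gata1-1 (27 of 45 lower and 3 higher, and 11 of 28 lower and 1 higher; 27 and 4, and 12 and 1, adjusted over the list alone), with adjusted p-values of 1.19e-05 and 0.00499. WRKY factors (6 of 13 higher and none lower), NBS-LRR proteins, which are immune receptors (12 of 21 higher and 4 lower), and water deficit and abscisic acid genes (29 of 75 higher and 9 lower) were higher, at adjusted p-values of 0.00491, 0.0105 and 0.00707 (9 and 0, 14 and 4, and 32 and 10 adjusted over the list alone). These 5 lists did not pass with an estimated correlation (adjusted p = 0.959 with an estimated correlation for each). MpNBS-LRR1 (Mp1g10650) stood at 48.2 ± 1.58 CPM in BoGa, 79.1 ± 5.21 in Mpb-gata1-1 and 163 ± 7.26 in Mpb-gata1-2 (SD, n = 3), whereas MpNBS-LRR21 (Mp7g19400) stood at 30.9 ± 2.29, 36 ± 0.995 and 7.88 ± 0.539 CPM. MpNBS-LRR13 (Mp4g22030; 39.0% unique reads) stood at 51 ± 4.42, 19.4 ± 1.21 and 28.5 ± 2.99 CPM. V-chromosome genes were higher in Mpb-gata1-2 (30 of 50, with 2 lower; adjusted p = 6.00e-15, and adjusted p = 0.559 with an estimated correlation), at V levels of 0.946 to 1.03 against 0.0172 to 0.0253.

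In all, 4534 genes differed between the mutants, 2189 higher and 2345 lower in Mpb-gata1-2 (2275 and 2247 with RLE factors), and 1070 of them differed at least 2-fold (538 higher and 532 lower). With the V level as a covariate, 347 genes passed and the median SE rose from 0.0942 to 0.447.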

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

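Of the tests below, those on the gemma genes and on the unique reads of MpGATA4, and the fits with the V level as a covariate, were chosen after the result was seen.

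The mutants differed from each other in 4534 genes by the edgeR test of the difference itself, and in 51 of the 99 genes named above. The log2 values that follow are fitted differences, Mpb-gata1-2 minus Mpb-gata1-1, and for genes without reads in a group, such as MpCupin8, MpPOD153 and MpVg00460, they depend on the prior count and give no bound. Among the class III peroxidases the difference was -10.00 for MpPOD153, -7.35 for MpPOD98, -6.69 for MpPOD160, -4.39 for MpPOD92, -4.18 for MpPOD90 and -0.68 for MpPOD80. Among cupins it was -10.08 for MpCupin8, -2.27 for MpCupin6, 1.46 for MpCupin63 and 4.57 for MpCupin35. V-chromosome genes gave 7.83 for MpVg00460, 8.57 for MpVg00600, 10.10 for MpVg00980 and 12.98 for MpVg01150.

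Defence-related genes gave -2.19 for MpNBS-LRR21, 0.55 for MpNBS-LRR13, 1.05 for MpNBS-LRR1, 1.20 for MpPR1a and 7.18 for MpPR6c, and the WRKY genes MpWRKY14 and MpWRKY8 gave 0.62 and 0.98. The LEA genes MpLEAL6, MpLEA-like2, MpLEA-like9 and MpLEA-like36 gave 0.49, 0.51, 0.79 and 0.79, beside 0.81 for MpCALEOSIN and 1.12 for MpCAT1. Enzyme genes gave -2.12 for MpCYP822-like6, 1.79 for MpCYP829-like12, 9.31 for MpCYP704-like8, 2.45 for MpDFR-like16, 4.47 for MpLOX4, 1.47 for MpMTPSL2 and -0.64 for MpPPO4. Cell wall and sugar enzyme genes gave -1.95 for MpGH19.10, -0.80 for MpExpansin4, 0.29 for MpGT77.1, 0.60 for MpGH3.5 and 1.02 for MpGH16.17. Developmental genes gave 4.37 for MpR2R3-MYB1, 0.75 for MpGCAM1, 0.42 for MpGRAS2, 0.16 for MpRKD, -0.27 for MpCEN1 and -0.49 for MpMID. The GATA genes gave 0.17 for MpGATA4, 0.31 for MpGATA5 and -0.23 for MpGATA1, and the remaining values were 0.40 for Mp4g00740, 0.39 for MpCKX2 and -0.47 for MpNPF9. By the camera test, 7 lists differed between the mutants: V-chromosome genes (adjusted p = 6.00e-15), class III peroxidases (2.00e-10), polyphenol oxidases (1.19e-05), WRKY factors (0.00491), expansins (0.00499), water deficit and abscisic acid (0.00707) and NBS-LRR proteins (0.0105), none of them with an estimated correlation (adjusted p = 0.559 to 0.959).

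The difference between the mutants runs with the V level, which was near 0 in Mpb-gata1-1 and intermediate in BoGa, as a mixture of plants with and without the V chromosome could give. If the same difference between plants set the autosomal genes, those genes would follow the V level among the BoGa libraries with a slope near 1, and in a simulated mixture the slope was 1.02. The slope was 0.00784 (-0.0794 to 0.0897) over the 1029 autosomal genes that differed 2-fold, which argues against it for these genes as a set. Single genes may still follow the V level. In the fit with the V level as a covariate, 32 autosomal genes had a slope on it that passed. The BoGa levels of MpCYP704-like8 and MpR2R3-MYB1 lay between those of the mutants, as the V level did. The slopes of these genes on the V level are not given here. Sequencing depth is also argued against, since 4253 genes differed with every library thinned to the smallest total. The lesions and the genetic background of each mutant line stay open, because the design gives 1 line for each allele.

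The water deficit and abscisic acid list had a median change of 1.81 in the mean of the mutants, with 56 of 75 genes higher and 8 lower, but it did not pass with an estimated correlation (adjusted p = 0.718). Scaling is argued against by the lowest median over TMM, RLE, upper-quartile and library-size scaling, 1.79. Shared reads are argued against by 54 of the list's members being higher with unique reads alone. The median was 1.80 with the V level as a covariate, but that fit cannot decide about the V level. BoGa lies between the mutants in V level, so the covariate hardly moves their mean against BoGa (Pearson's r with the main fit 0.997 over all genes). Most genes of the list were higher in each mutant, on either side of BoGa in V level, which argues against a change that follows the V level. With limma on log2 of TPM or RPKM plus 1 the median was 1.33 and 0.97, with 56 genes higher and 5 lower in each, and the added 1 shrinks changes of genes with low values by its construction. A larger share of gemma tissue in the mutant plants could also bring such transcripts, since gemmae are known to be dormant, and cannot be told apart. The 4 genes listed for gemma cups and gemmae had a median of 0.39. MpGCAM1, MpGRAS2 and MpKAR rose and MpCLE2 fell, and how far each of them marks gemma tissue was not tested. A rise caused by the mutations in MpB-GATA1 is the biological hypothesis the design offers, and it was not tested apart from the gemma tissue. With 1 line for each allele, it also cannot be told apart from the genetic background of the lines.

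Reads of MpGATA4 were higher in the mutants of the gene it is taken to be. Reads from paralogs are argued against by a log2 change of 0.82 with unique reads, and scaling by a lowest change of 0.80 over the scalings named above. More transcript from the mutated gene, through altered transcription or stability, may therefore be a biological effect, as a hypothesis found and tested on the same data, and where in the gene the lesions lie was not analysed here.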

How the results depend on the processing

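The fits with the V level as a covariate and without V-chromosome genes were chosen after the data had been seen; the others were planned. Counts of changed genes stayed within 1.5 times the main count under RLE or upper-quartile factors, DESeq2, no filter, the stricter filter, only the groups compared, limma on TPM or RPKM, unique reads and without V-chromosome genes. No result for a single gene reversed. The balance of higher and lower genes did reverse in each comparison under at least 1 setting: for the mean of the mutants against BoGa it was 3330 higher and 3824 lower with TMM, but 4582 and 2545 with limma on TPM. Several gene lists also changed their balance with the scaling, and the cause was not tested. Of 260 results for single genes, 108 were the same under every setting run, and of 6505 checks 6121 were the same, 377 lost the call and 7 gained it.

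Stricter thresholds lowered the counts by their construction. With a test against a 1.5-fold change, 1050 genes passed for Mpb-gata1-1 against BoGa, 1166 for Mpb-gata1-2 against BoGa, 1023 for their mean, 946 between the mutants, and 485 alike in both mutants. With an adjusted p and a 2-fold difference these were 1229, 1297, 1118, 1070 and 594, and MpGATA4, at 0.82, did not pass. At an adjusted p under 0.01 the counts were 4453 for Mpb-gata1-1, 2612 between the mutants and 2490 alike in both. With the V level as a covariate they were 1856 for Mpb-gata1-1, 1517 for Mpb-gata1-2, 347 between the mutants and 179 alike in both, but 7556 for their mean against BoGa. Because the V level nearly coincides with the groups, the median SE of the difference between the mutants rose from 0.0942 to 0.447 in that fit, while for the mean of the mutants against BoGa it was 0.0813 and 0.0740. Of the gene lists, 8 passed for the mean of the mutants against BoGa, 0 did with an estimated correlation, and 26 passed with fry, which tests each list by itself and does not compare it with other genes. For these changes in the number of lists the cause was not tested beyond the construction of each test.

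Leaving out each library in turn gave 5413 to 7045 genes for Mpb-gata1-1, 5558 to 7160 for Mpb-gata1-2, 5883 to 7259 for their mean, 3211 to 5560 between the mutants and 3249 to 4391 alike in both. MpGATA4 stayed at 0.81 to 0.84 and the correlation at 0.505 to 0.557. The number of lists was 5 to 9, with 5 without Mpb-gata1-2 replicate 3, and the cause was not tested. All 24 genes ranked for the mean of the mutants kept their call without each library, and 23 did with unique reads, since MpRLK-Pelle_WAK1 has none, and under the stricter filter.

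The labels do not say whether libraries with the same replicate number share more than that number. Their deviations from the group means correlated at -0.116 to 0.161, against -0.168 to 0.186 for different numbers. With 3 libraries in each group, these ranges cannot exclude a shared batch. With the replicate number as a block, 6273, 6368, 6660 and 4065 genes passed for Mpb-gata1-1, Mpb-gata1-2, their mean and between the mutants, 3682 alike in both, the correlation was 0.526, 8 lists passed, MpGATA4 rose by 0.82 and MpMID did not pass (adjusted p = 0.0766). Leaving out organelle genes was not run, since none were in the tables used here, and the fit to only the groups compared does not apply to the mean of the mutants against BoGa. Depth limits genes with few reads, for which floors or intervals are given.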

Other observations

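Of the tests in this part, the splits of the libraries and the search for runs of neighbouring genes were planned before their results were seen.

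Nitrogen transport genes were lower more often than higher in the mean of the mutants against BoGa, with 9 of 31 lower and 5 higher (9 and 5 adjusted over the list alone), but the list did not pass the camera test (adjusted p = 0.333). MpNPF5 (Mp3g03470), of the nitrate and peptide transporter family, fell by 1.36 ± 0.07 (log2, SE), from 21.3 ± 0.929 CPM in BoGa to 7.92 ± 0.509 in Mpb-gata1-1 and 8.79 ± 0.654 in Mpb-gata1-2 (SD, n = 3). MpNPF9 (Mp3g09240) fell by 1.61, from 38 ± 8.43 to 14.6 ± 0.488 and 10.6 ± 1.13 CPM.

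Of 10 genes of cytokinin and two-component signalling, 5 were lower and 1 higher (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.388). MpCKX2 (Mp5g10910), which encodes a cytokinin-degrading enzyme, fell by 1.18, from 6.03 ± 0.612 CPM to 2.32 ± 0.0183 in Mpb-gata1-1 and 3.02 ± 0.276 in Mpb-gata1-2 (SD, n = 3). MpLOG (Mp1g00270), which encodes a cytokinin-activating enzyme and overlaps another gene, fell by 0.70. The receptor gene MpCHK2 (Mp6g00310) rose by 0.69, from 11.4 ± 0.212 to 18.2 ± 1.25 and 18.6 ± 1.43 CPM.

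Genes that differed at least 16-fold between the mutants tended to lie near each other. Of 109 such autosomal genes, 24 had another of the same sign within 5 tested genes when members of a named family were counted once (26 without that rule). Unnamed genes, which many of the 109 are, were not sorted into families, so unnamed duplicates lying side by side still count. In 1000 random sets the median was 4 and the highest 14, a permutation p of 0.001, which is the smallest these sets can give. On chromosome 2, for example, Mp2g05420 and Mp2g05440, chosen after their values were seen, had no reads in Mpb-gata1-2, with fitted differences of -8.16 and -11.43, while MpCupin35 between them was higher there. Segments of different parental origin in the mutant lines, or local deletions, may give such runs, and neither was tested. Of the 50 tested genes nearest to MpGATA4, 16 differed between the mutants, 3 of them 2-fold, and 27 differed between both mutants and BoGa, none of them 2-fold. Over all tested genes 30.9% differed between the mutants and 48.8% between their mean and BoGa. The counts near MpGATA4 lie close to these shares.

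Other splits of the 9 libraries into groups of the same sizes were drawn, 100 for each result. For genes changed in the mean of the mutants against BoGa, 1 split, the real one, gave as many as 7154. The highest of the others gave 4510, and their median was 0. Most other splits mixed libraries of different groups, which widens the spread within a group and lowers the count by construction. That other split kept the BoGa libraries together and mixed the mutants. For genes changed alike in both mutants the real split gave 4015 (1 of 100) and the highest other, that same split, gave 2783. Chance can be excluded for the grouping of the libraries by label, but the splits cannot tell the mutations from other differences between the lines. Groups of mixed mutants also shared many genes, so the splits do not show that the agreement is specific to the 2 alleles. The covariance of the log2 changes was 0.472 and 3 of 100 splits gave as much, under the share of 0.05 at which chance can be excluded. The other splits as large gave more (0.625 and 0.627), each with a whole group as the controls, so the splits do not show that the covariance is specific to the real grouping of the mutants; the simulations without an effect had a median of 0.0202. The number of gene lists that passed was 8, but 29 of 100 splits gave as many, up to 13, so chance cannot be excluded for that number. For the comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05: the real values were 6746, 6811 and 4534 for Mpb-gata1-1 and Mpb-gata1-2 against BoGa and between the mutants (1 split each), and the highest others were 0, 1 and 0.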
